A study of Medicago truncatula with 6 samples.

How the data were processed

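RNA sequencing was done on mycorrhizal roots of Medicago truncatula, wild type R108 and Mtphr2, with 3 libraries per genotype. Per the labels' protocols, RNA was extracted with TRIzol, libraries were read on an Illumina NovaSeq 6000, and reads were mapped to version 4.0 of the Medicago truncatula genome. Per the submitters' processing notes, HISAT2, StringTie and DESeq2 were used. Their versions and the program that counted reads are not given in the sources used here.

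The deposited table holds expected counts, also called estimated counts, for 54762 loci in 6 libraries, with 2 decimals. Of these loci 51519 are annotated genes, 1915 are assembled loci outside the annotation and 1328 are RNA genes. Over loci with a count in any library, 81.3% to 82.5% of a library's values were whole to 2 decimals. Totals per library ran from 18199040 to 21477169, and 26859 to 27375 loci had a value above 0. The 20 most abundant genes took 5.50% to 6.11% of a library, assembled loci 1.37% to 1.63% and RNA genes 0.409% to 0.601%. The estimated counts were rounded to whole numbers for the count models. Gene descriptions and closest Swiss-Prot entries are those of the deposited table. A reference gene table of another assembly was not used.

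Tests were run in R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1, and with the data.table package at version 1.17.8 to read files, and figures were drawn with matplotlib 3.10.9. Genes were kept with filterByExpr of edgeR at its defaults (minimum count 10, minimum total 15), which left 22663. Library sizes were scaled by TMM, with factors of 0.955 to 1.02. Genotypes were compared by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, and a fold of at least 2 was used as a size threshold. The common biological coefficient of variation was 0.275, and the median log2 fold change of all tested genes was 0.02. With other scalings that median was 0.002 with DESeq2 size factors, 0.039 with library size alone and 0.02 with upper-quartile factors, and no list that passed changed the sign of its median. CPM values, the count scaled to a common library size, use the TMM-scaled library sizes. For genes without counts in a genotype, a floor of 3 counts per library gives the smallest fold.

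Lists of genes were fixed before the data were examined, 3 by locus and 46 by words in the annotation. A gene could be in several lists, so the lists are not independent. All 33 loci matched an annotation of the right kind and 32 were tested. The 48 lists with at least 5 tested members were tested by camera with a preset correlation of 0.01 on log2 CPM with a prior count of 2, and by fry. A pair of lists, whose words also match unrelated families, was not read. Words for the PHR family also match photolyases and other proteins, and the 9 genes reported are those left after photolyases, photoreceptors and proteins named for altered phosphate starvation responses or rolled leaves were taken out. Annotation terms with 10 to 500 tested genes were tested by a one-sided Fisher's exact test among called genes, against the 19777 tested genes that carry any term.

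Genes were named by a rule written before the data were examined. It names every gene of the lists by locus and of the PHR family that passed the filter. It also names the 10 highest and 10 lowest fold changes among called genes with a functional description, at least 5 CPM in the higher genotype and no overlap between genotypes, and up to 3 called members of each list. Its use for calls made with the replicate block was chosen after the data were examined, and genes outside it are marked as such in the text.

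The titles number the libraries 1 to 3 in each genotype. After the genotype means were removed, libraries of the same number correlated at 0.377, 0.151 and 0.168 across genes, each above 0.1. Libraries of different numbers correlated at -0.31 to 0.187 between genotypes, and the highest of these, for R108 replicate 3, was above the same-number values of 0.151 and 0.168. Since all same-number values were above 0.1, a fit with the replicate number as a term (the replicate block) is given where it changes a call. The replicate block called 76 genes against 18 with no block. Genes are not independent replicates in these correlations. Duplicate libraries of 1 RNA sample would have a chi-square per degree of freedom near 1 between libraries of a genotype, and the 6 pairs had 25.1 to 51.7.

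The tests were tested on simulated data with the spread and depth of these libraries, in which 200 of 22663 genes were changed. The main edgeR test recovered 15% of genes changed 2-fold and 74% of those changed 4-fold, and 11% of its calls were false. With the replicate block these values were 4%, 60% and 9.86%, and with DESeq2 62%, 87% and 35.2%. No effect of the replicate number was simulated, so the block had nothing to remove. Its values therefore do not describe data that hold such an effect. Camera put 2 of 100 unchanged lists at an unadjusted p under 0.05. Genes were simulated independently, so this does not test camera on lists whose genes move together. In the real data the estimated correlation had a median of 0.031 over lists and was 0.927 for the list of arbuscule markers.

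Alternatives tried were other scalings, low-count filters, tests and dispersion schemes, the replicate block, each library left out in turn, and the 20 most abundant genes left out. No library was left out of the reported values.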

Results

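Transcript levels were measured by RNA sequencing in mycorrhizal roots of Medicago truncatula, a model legume whose roots host arbuscular mycorrhizal fungi. There were 3 libraries from the wild-type line R108 and 3 from the Mtphr2 mutant. Deposited estimated counts summed to 19310625, 19396774 and 18199040 in R108 replicates 1, 2 and 3, and to 19809184, 21477169 and 20915643 in Mtphr2 replicates 1, 2 and 3. Of 54762 loci, 22663 had enough counts to be tested, of which 21548 were annotated genes, 1080 were assembled loci outside the annotation and 35 were RNA genes. The labels call the 3 libraries of a genotype technical replicates, so every p-value here measures only the spread between these libraries. All errors are SD over n = 3 libraries unless a standard error (SE) is named.

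PHR proteins are MYB-type transcription factors that control the phosphate starvation response. The sources used here do not say which locus is mutated in Mtphr2, so the genotype labels were not checked by its level. The words used for the PHR family picked out 9 genes, of which 6 were tested. They do not match entries named PHL, so the 9 are not a full count of the family. MYB1 (MTR_7g068600), whose closest Swiss-Prot entry is PHL5, is given with the arbuscule markers below. MTR_7g098250, whose closest Swiss-Prot entry is PHOSPHATE STARVATION RESPONSE 1, had 89.3, 80.4 and 83.0 CPM, the count scaled to a common library size, in R108 replicates 1 to 3 and 94.2, 85.0 and 97.3 CPM in Mtphr2 replicates 1 to 3. In the same order, the PHR1-LIKE 1 gene MTR_7g115530 had 60.8, 60.4 and 49.5 against 84.3, 79.6 and 75.04 CPM, and the PHR1-LIKE 1 gene MTR_1g080330 had 30.7, 34.7 and 31.0 against 39.6, 38.0 and 37.8 CPM. The PHR1-LIKE 2 gene MTR_2g027800 had 62.9, 46.8 and 52.7 against 53.8, 47.5 and 44.1 CPM, and the PHR1-LIKE 2 gene MTR_1g090670 had 17.6, 22.5 and 24.4 against 21.0, 18.7 and 20.8 CPM. The MYB-CC gene MTR_4g097835 had 5.48, 5.59 and 1.46 against 1.20, 0.74 and 0.71 CPM. The 3 untested genes had at most 1 estimated count in any library. Of the 6 tested genes, 0 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, although 3 had an unadjusted p under 0.05. DESeq2 called 2 of them, MTR_4g097835 (adjusted p = 0.0101) and MTR_7g115530 (adjusted p = 0.0181), and limma-voom called 0.

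The comparison asked which genes differ between R108 and Mtphr2 when roots are mycorrhizal. A papain family cysteine protease, MTR_3g116080, whose closest Swiss-Prot entry is XCP2, a protease of xylem cells, had 107.9 ± 17.5 CPM in R108 and 2.88 ± 0.770 CPM in Mtphr2, a 37.4-fold fall. A Myb/SANT-like DNA-binding protein, MTR_2g018710, fell 7.10-fold, from 44.1 ± 6.62 to 6.22 ± 1.47 CPM. A NADPH:quinone oxidoreductase-like gene, MTR_3g019090, rose 2.57-fold, from 43.1 ± 4.24 to 111 ± 7.92 CPM. An arogenate/prephenate dehydratase, MTR_2g084875, of the enzyme family that makes phenylalanine, rose 2.02-fold, from 53.6 ± 3.73 to 108.2 ± 5.34 CPM.

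In all, 18 genes passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05. Of these, 11 were higher and 7 lower in Mtphr2, and 17 differed at least 2-fold. The 8 annotated genes among them were 5 higher and 3 lower. MTR_3g116080 had a log2 fold change of -5.22 (SE 0.249, adjusted p = 0.00162 by edgeR) and kept its call in all 6 fits that left out 1 library. MTR_2g018710 had -2.83 (SE 0.213, adjusted p = 0.0186 by edgeR), with adjusted p of 0.110 without R108 replicate 2, 0.113 without R108 replicate 3 and 0.165 without Mtphr2 replicate 3. The wall-associated kinase gene MTR_5g055310 rose 1.93-fold, from 13.7 ± 0.0717 to 26.5 ± 0.454 CPM (adjusted p = 0.0370 by edgeR). The F-box protein gene MTR_2g021190 rose 2.60-fold, from 5.87 ± 0.467 to 15.3 ± 1.13 CPM (adjusted p = 0.0372 by edgeR). A putative transmembrane protein gene, MTR_6g053230, had no counts in R108 and 6.12 ± 0.266 CPM in Mtphr2, at least 38.3-fold higher with a floor of 3 counts per library (adjusted p = 0.0194 by edgeR). The hypothetical protein gene MTR_3g030400, named after its values were seen, fell from 11.9 ± 2.29 to 0.160 ± 0.0273 CPM (adjusted p = 0.00137 by edgeR), and the plot of differing annotated genes shows the fitted changes.

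**Figure D1:**
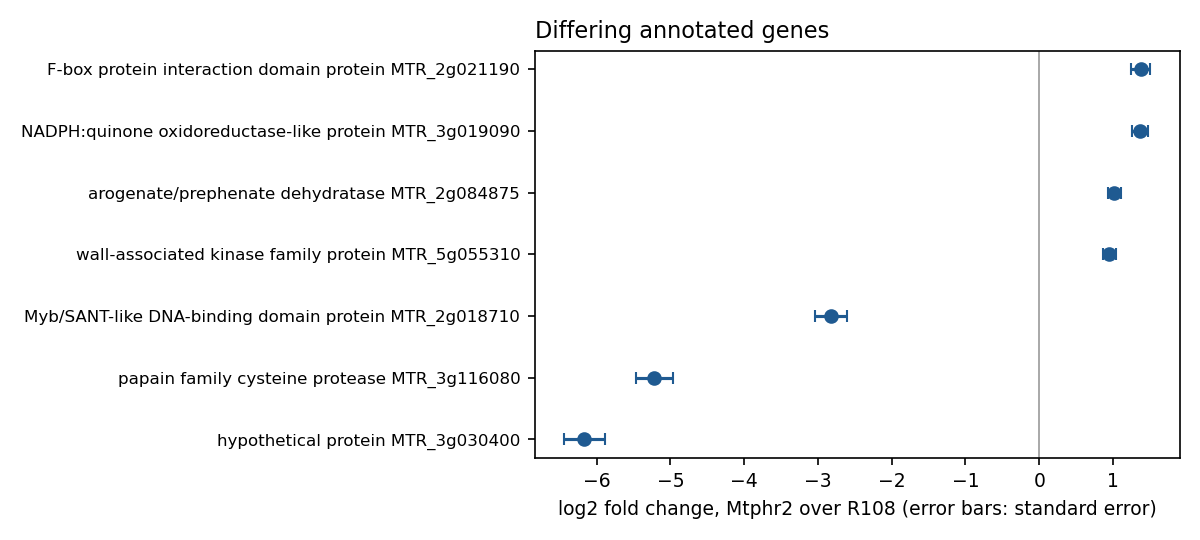
Log2 fold change of Mtphr2 over R108 for the annotated genes that passed edgeR's test and had counts in both genotypes. Points are fitted values, bars are standard errors, and MTR_3g030400 lies lowest at -6.17.

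The calls of the 5 annotated genes that rose ended when single libraries were left out, although their fitted changes stayed close. With 1 library left out, log2 fold changes ran from 0.96 to 1.06 for MTR_2g084875, from 0.93 to 0.96 for MTR_5g055310 and from 1.30 to 1.44 for both MTR_2g021190 and MTR_3g019090. For MTR_2g084875, MTR_5g055310 and MTR_2g021190, leaving out any 1 of R108 replicates 1, 2 and 3 or Mtphr2 replicates 1, 2 and 3 ended the call, with adjusted p from edgeR of 0.0530 to 0.202 for MTR_2g084875 and of 0.0585 to 0.251 for both others. For MTR_3g019090 (adjusted p = 0.0191 by edgeR in all libraries) the value was 0.0566, 0.0582 and 0.135 without R108 replicates 1, 2 and 3, and 0.111 and 0.153 without Mtphr2 replicates 2 and 3. For MTR_6g053230 it was 0.0582 and 0.0511 without R108 replicates 2 and 3, and 0.0546, 0.160 and 0.202 without Mtphr2 replicates 1, 2 and 3. With the replicate block, a term for the replicate number, MTR_2g084875 (adjusted p = 0.0350) and MTR_3g019090 (adjusted p = 0.0426) passed edgeR's test, while MTR_5g055310 (0.0532), MTR_2g021190 (0.0556) and MTR_6g053230 (0.0650) did not. The number of calls ran from 7 to 44 when 1 library was left out, with 8 without R108 replicate 2 or 3, 44 without Mtphr2 replicate 1 and 7 without Mtphr2 replicate 2 or 3. It was 76 with the replicate block (26 higher and 50 lower, of which 66 were annotated and 13 shared with the 18), 1298 by DESeq2 (628 higher, 670 lower) and 31 by limma-voom (20 higher, 11 lower). Over all 22663 tested genes, 3722 had an unadjusted p under 0.05 by edgeR with no block.

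The other 10 of the 18 were loci assembled from the reads outside the annotation, 6 higher and 4 lower in Mtphr2. The examples here were chosen after their values were seen. MSTRG.16113 fell from 38.4 ± 2.13 to 1.27 ± 0.179 CPM, with a log2 fold change of -4.92 (adjusted p = 4.68e-04 by edgeR). MSTRG.26295 fell from 31.6 ± 3.52 to 3.12 ± 0.185 CPM (adjusted p = 0.00137 by edgeR). MSTRG.2804 rose from 0.213 ± 0.109 to 19.3 ± 2.84 CPM (adjusted p = 0.00186 by edgeR). All 3 kept their call whichever library was left out. MSTRG.26197 had no counts in R108 and 6.94 ± 0.312 CPM in Mtphr2, at least 43.5-fold higher, but its adjusted p by edgeR was 0.0650 with the replicate block and reached 0.202 with 1 library left out, its call ending without R108 replicate 2, Mtphr2 replicate 2 or Mtphr2 replicate 3.

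A list of 17 genes known to mark the arbuscule, the branched fungal structure inside root cells, was fixed before the data were examined. All 17 had lower fitted levels in Mtphr2, by 3.69-fold for the GRAS factor gene RAD1 to 7.42-fold for the sugar transporter gene SWEET1b. PT4 (MTR_1g028600), the phosphate transporter of the arbuscule membrane, had 1705, 819 and 404 CPM in R108 replicates 1 to 3 and 403, 38.3 and 89.0 CPM in Mtphr2 replicates 1 to 3. RAM1 (MTR_7g027190), a GRAS factor needed for arbuscule branching, had 163, 83.7 and 34.3 against 36.0, 6.63 and 8 CPM in the same order. MYB1 (MTR_7g068600), a factor that acts in arbuscule degeneration, had 1307, 574 and 333 against 257, 6.82 and 36.9 CPM. The spread inside each genotype was of the same size as the difference, with a median range over the markers of 5.73-fold among R108 libraries and 5.09-fold among Mtphr2 libraries. The mean log2 CPM of the markers was 5.84 ± 1.25 in R108 and 3.37 ± 1.30 in Mtphr2, a difference of -2.47, with p = 0.2 in a two-sided exact permutation test that could not go below 0.1. Within libraries of the same number the differences were -2.24, -3.63 and -1.55, all of 1 sign, with p = 0.25 in a two-sided exact sign-flip permutation test that could not go below 0.25. In R108 replicate 3 this mean was 4.56, below the 4.81 of Mtphr2 replicate 1, as the plot of marker levels shows.

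**Figure D2:**
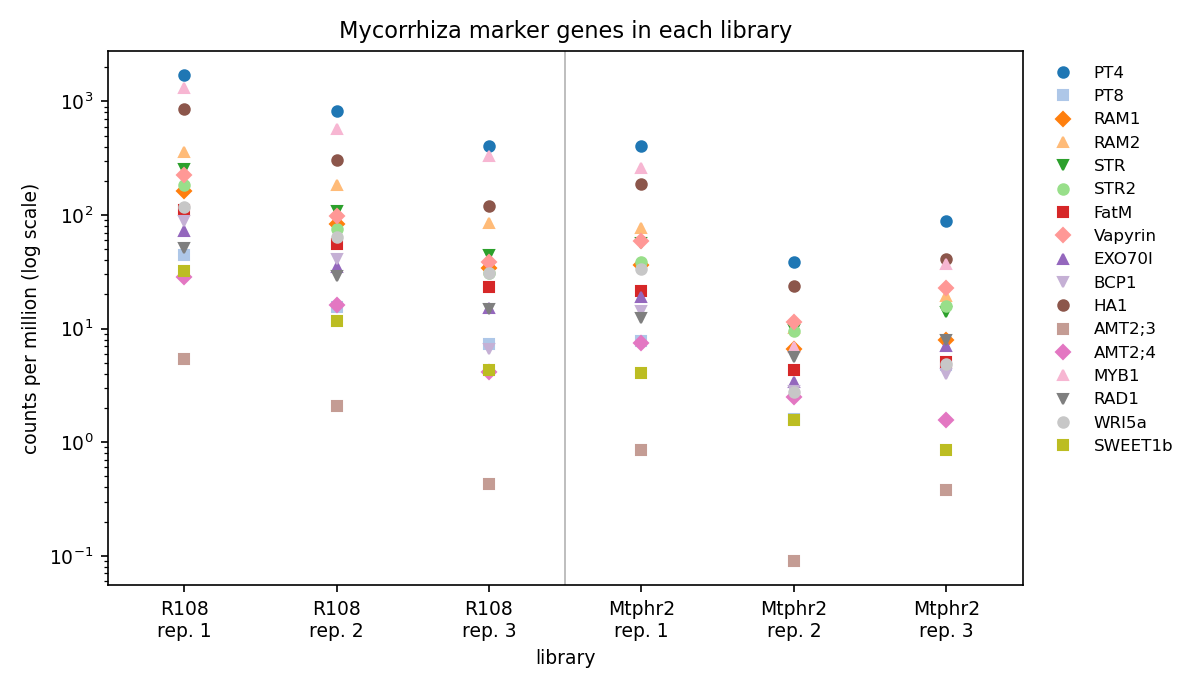
Level of 17 arbuscule marker genes in each of the 6 libraries, in CPM on a log scale, 1 symbol per gene. Levels fall from replicate 1 to replicate 3 in R108, and Mtphr2 replicate 1 lies near R108 replicate 3.

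Of the 17 markers, 0 passed edgeR's quasi-likelihood test over all genes, with adjusted p of 0.206 to 0.320, and 0 passed when adjusted over the list alone. An unadjusted p under 0.05 was found for 14, DESeq2 called 4 (RAD1, SWEET1b, PT8 and EXO70I) and limma-voom called 0. In 6 of the 17 every R108 library lay above every Mtphr2 library, where chance separates 10% of genes one way or the other and 22.2% of all tested genes were separated. With the replicate block, SWEET1b (MTR_3g089125) fell with a log2 change of -2.78 (adjusted p = 0.0345 by edgeR), and all 17 passed when adjusted over the list alone. As a list, the markers were lower relative to other genes by camera (median log2 fold change -2.37, adjusted p = 9.08e-09), and adjusted p = 0.598 with an estimated correlation.

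The plant's symbiosis signalling genes, 12 loci of which 11 were tested, were also lower as a list (median log2 fold change -0.56, camera adjusted p = 0.0387, and adjusted p = 0.749 with an estimated correlation). The list holds genes of rhizobial signalling, such as NFP and ERN1, beside genes of the common pathway. Of the latter, DMI1, DMI2, DMI3 and IPD3 had log2 fold changes of -0.343, 0.039, -0.555 and -0.268. Of the 11, 9 had negative and 2 positive log2 fold changes. ERN1 (MTR_7g085810), a transcription factor of rhizobial infection, had 7.31 ± 5.46 CPM in R108 and 2.07 ± 0.633 in Mtphr2. DELLA1 (MTR_3g065980), a repressor of gibberellin responses that promotes arbuscule formation, had 133 ± 13.6 and 101 ± 10.3 CPM. The receptor kinase gene DMI2 (MTR_5g030920) had 136 ± 50.1 and 139 ± 17.3 CPM. None of the 11 passed edgeR's test over all genes, and 0 passed when adjusted over the list alone, with 3 at unadjusted p under 0.05, 0 called by DESeq2 and 0 by limma-voom. With the mean marker level as a covariate, an alternative chosen after the data were examined, the median turned to 0.31 (camera adjusted p = 0.434). The camera adjusted p of the list was 0.531 without R108 replicate 1, 0.137 without Mtphr2 replicate 2 and 0.148 with a filter at a mean of 10 CPM.

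Strigolactones are carotenoid-derived signals that roots release to the fungus. All 4 synthesis genes had lower means in Mtphr2. D27 (MTR_1g471050) had 82.7 ± 52.5 CPM in R108 and 25.1 ± 15.2 in Mtphr2, and CCD8 (MTR_3g109610) had 84.6 ± 39.2 and 41.6 ± 9.13 CPM. The log2 fold changes of CCD7 and MAX1 were -0.58 and -0.42. Of the 4, 0 passed edgeR's test over all genes and 0 passed when adjusted over the list alone, with 2 at unadjusted p under 0.05, 1 called by DESeq2 (D27) and 0 by limma-voom. Under the replicate block, 2 passed when adjusted over the list alone, D27 and CCD8. With the mean marker level as a covariate the median of the list turned from -0.80 to 0.20. The list was too short for camera.

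Genes of phosphate starvation, 92 tested members of which 50 had negative and 42 positive log2 fold changes, did not pass as a list (median -0.03, camera adjusted p = 0.230). Over all genes 0 passed edgeR's test and 0 passed when adjusted over the list alone, with 11 at unadjusted p under 0.05, 6 called by DESeq2 (1 higher, 5 lower) and 0 by limma-voom. Only with the replicate block did 2 fall by edgeR's test, both with adjusted p = 0.0426, and 8 passed when adjusted over the list alone (1 higher, 7 lower). An IDS4-like gene, MTR_3g107393, whose closest Swiss-Prot entry is an SPX domain protein of phosphate sensing, had 145 ± 88.9 CPM in R108 and 29.4 ± 25.9 in Mtphr2 (log2 change -2.45). A gene for an inactive purple acid phosphatase-like protein, MTR_4g037670, had 54.7 ± 47.4 and 10.5 ± 8.92 CPM (log2 change -2.35). With the mean marker level as a covariate neither passed edgeR's test, with log2 changes of -0.43 (adjusted p = 0.768) for MTR_3g107393 and -0.10 (adjusted p = 0.932) for MTR_4g037670. The arbuscule markers PT4 and PT8 are also in the phosphate starvation list, and PT8 is among its members that DESeq2 called lower.

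Among 45 tested cysteine protease genes, MTR_3g116080 alone fell by edgeR's test, both over all genes and adjusted over the list alone. DESeq2 called 4 (1 higher, 3 lower), and limma-voom called 1. In the fit with the replicate block 7 fell, of which 6 had SAG39, a senescence-linked protease, as closest Swiss-Prot entry, and 11 passed when adjusted over the list alone (1 higher, 10 lower). DESeq2 gave no adjusted p for 5 of these 7, so its count of calls leaves them out. One of these 6, MTR_4g107930, had 240.2, 21.7 and 21.2 CPM in R108 replicates 1 to 3 and 14.6, 0.87 and 0.76 CPM in Mtphr2 replicates 1 to 3. Its log2 fold change with the replicate block was -4.38 (adjusted p = 0.0175 by edgeR), against an adjusted p of 0.277 with no block. MTR_4g047610, another, had -4.36 with the replicate block (adjusted p = 0.0293 by edgeR). As a list the proteases had a camera adjusted p of 0.204, and of 0.0268 with the replicate block, where adjusted p = 0.489 with an estimated correlation.

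Of 36 tested chitinase genes, 0 passed edgeR's test over all genes and 0 when adjusted over the list alone, with 12 at unadjusted p under 0.05, 5 called by DESeq2 (2 higher, 3 lower) and 0 by limma-voom. Adding the replicate block to edgeR's test, 2 fell over all genes, and 7 passed when adjusted over the list alone (2 higher, 5 lower). MTR_6g079630 had 111, 9.28 and 10.6 CPM in R108 replicates 1 to 3 and 6.58, 0.51 and 0.76 CPM in Mtphr2 replicates 1 to 3, a log2 change of -4.02 with the replicate block (adjusted p = 0.0107 by edgeR). MTR_8g055940 had -4.11 (adjusted p = 0.0322 by edgeR), and DESeq2 gave no adjusted p for either gene. The list's median was 0.28 and its mean -0.41, and camera gave the direction up (adjusted p = 0.793). Of the 7 proteases and 2 chitinases that fell with the block, 6 had estimated counts that were not whole to 2 decimals in at least 1 library, against 26.5% of all tested genes, and the plot of these genes shows the steep fall from R108 replicate 1.

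**Figure D3:**
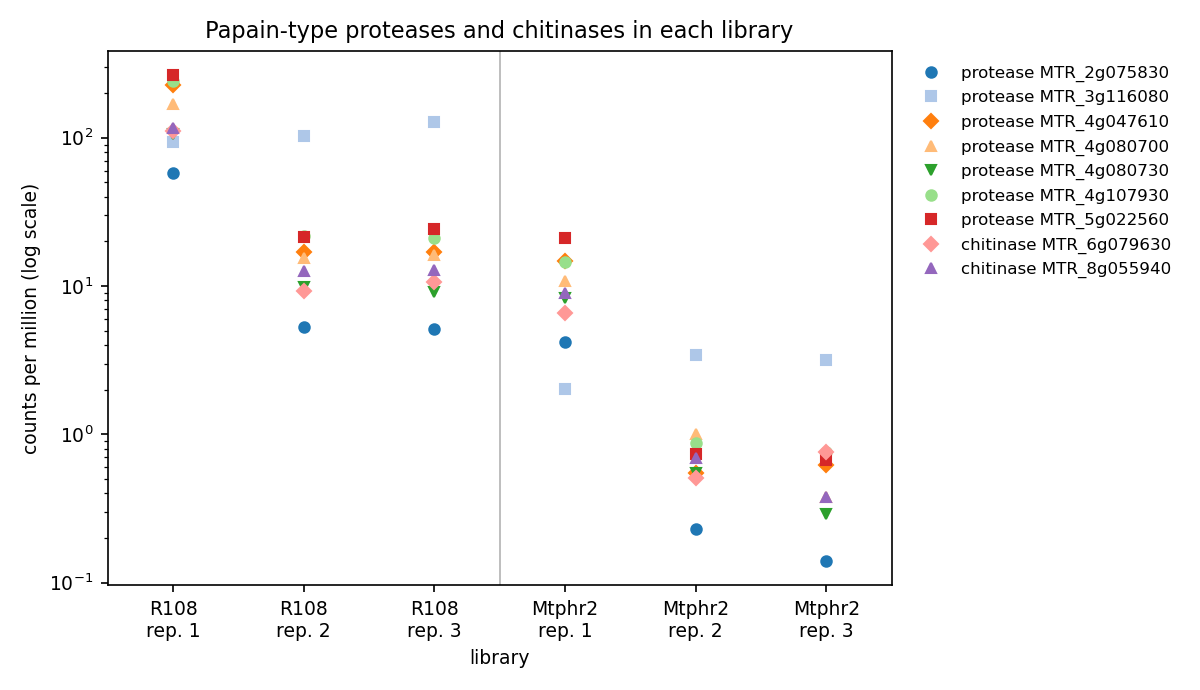
Level of 7 papain-type protease genes and 2 chitinase genes in each of the 6 libraries, in CPM on a log scale, 1 symbol per gene. The protease MTR_3g116080 stays between 94.1 and 128 CPM in all R108 libraries, while the others are highest in R108 replicate 1.

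Other genes passed edgeR's test with the replicate block and not by genotype alone, and 6 of them are given here as examples, picked after their values were seen. A Kunitz-type trypsin inhibitor gene, MTR_6g059650, rose from 113 ± 37.6 to 367 ± 166 CPM (block adjusted p = 0.0314 by edgeR). A NAC factor gene, MTR_3g096920, rose from 29.3 ± 3.38 to 62.0 ± 13.03 CPM (block adjusted p = 0.0443 by edgeR), and a GRAS factor gene, MTR_2g097463, from 61.2 ± 17.2 to 128 ± 27.9 CPM (block adjusted p = 0.0426 by edgeR). A methyl jasmonate esterase gene, MTR_5g018320, fell from 51.4 ± 15.6 to 14.4 ± 3.82 CPM (block adjusted p = 0.0245 by edgeR). A soluble acid invertase gene, MTR_4g101630, which splits sucrose in the vacuole, fell from 223 ± 63.2 to 72.3 ± 26.0 CPM (block adjusted p = 0.0429 by edgeR). A ripening-related gene close to kiwellin, MTR_7g012350, fell with a log2 change of -4.38 (block adjusted p = 0.0314 by edgeR). Without the block the adjusted p of these 6 genes ran from 0.117 to 0.251, and with the mean marker level as a covariate MTR_7g012350 had a log2 change of -1.21 (adjusted p = 0.638 by edgeR).

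Of 48 lists tested by camera, 13 passed at an adjusted p of 0.05, 9 lower and 4 higher in Mtphr2, and none of these calls held with an estimated correlation. Among genes with a mean of at least 10 CPM 13 lists passed as well, but 5 were lower and 8 higher, and 9 were shared. Directional fry, which tests whether a list moved one way and not whether it moved more than other genes, called 2 lists, and 0 with the replicate block. Only the lists of arbuscule markers, fatty acid synthesis, carotenoid and MEP pathway genes, WRKY factors and ribosomal proteins kept their camera call whichever library was left out. Over all 22663 tested genes, 3722 had an unadjusted p under 0.05 by edgeR and 1298 were called by DESeq2. The counts of list members at these thresholds were not tested against those over all genes.

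Fatty acid synthesis genes, which supply the lipid passed to the fungus, were lower as a list (48 tested, 38 negative and 10 positive, median -0.34, camera adjusted p = 4.16e-06, and adjusted p = 0.510 with an estimated correlation). No member passed edgeR's test over all genes and 2 passed when adjusted over the list alone (1 higher, 1 lower), with 25 at unadjusted p under 0.05, 12 called by DESeq2 (2 higher, 10 lower) and 0 by limma-voom. Under the replicate block 24 passed when adjusted over the list alone (2 higher, 22 lower). The 2 were the stearoyl-acyl-carrier desaturase gene MTR_1g029150, which rose from 4.41 ± 0.377 to 10.2 ± 1.54 CPM, and the acyl carrier protein gene MTR_7g080760, which fell from 89.1 ± 2.30 to 68.5 ± 2.47 CPM. With the mean marker level as a covariate the list's median was -0.17 and its camera adjusted p was 0.0696. The arbuscule marker FatM is also in this list. A biotin carboxyl carrier gene of acetyl-CoA carboxylase, MTR_6g015020, had 239 ± 111 CPM in R108 and 92.7 ± 30.5 in Mtphr2, and a ketoacyl reductase gene, MTR_3g085740, had 322 ± 121 and 155 ± 31.8 CPM. These genes, and the list members not called over all genes that are given as examples in the paragraphs on the other lists, were chosen after their values were seen.

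Carotenoid and MEP pathway genes were lower as a list (30 tested, 26 negative and 4 positive, median -0.47, camera adjusted p = 3.43e-04, and adjusted p = 0.493 with an estimated correlation). Over all genes 0 passed edgeR's test and 1 fell when adjusted over the list alone, with 12 at unadjusted p under 0.05, 2 called by DESeq2 and 0 by limma-voom. Under the replicate block 12 did so (1 higher, 11 lower). The gene that fell without the block was the carotenoid cleavage dioxygenase gene MTR_5g025250, at 1.005 ± 0.315 CPM in R108 and 0.0321 ± 0.0279 in Mtphr2. The phytoene synthase gene MTR_3g083630 had 207 ± 145 and 45.5 ± 35.4 CPM. The strigolactone genes CCD7 and CCD8 are also in this list. The list's median was -0.07 with the mean marker level as a covariate (camera adjusted p = 0.585).

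Gibberellin genes were lower as a list (41 tested, 27 negative and 14 positive, median -0.52, camera adjusted p = 0.0387, and adjusted p = 0.493 with an estimated correlation). The receptor gene MTR_1g102170, a GID1, had 41.7 ± 2.87 CPM in R108 and 27.9 ± 4.44 in Mtphr2, and the gibberellin 20-oxidase gene MTR_1g102070 had 27.3 ± 8.41 and 14.4 ± 1.70 CPM. None passed edgeR's test over all genes and 0 did when adjusted over the list alone, with 9 at unadjusted p under 0.05, 2 called by DESeq2 and 0 by limma-voom, and with the replicate block 3 fell when adjusted over the list alone. The list's camera adjusted p was 0.133 without R108 replicate 1, 0.0666 without R108 replicate 2 and 0.0617 with a filter at a mean of 10 CPM, and 0.717 with the mean marker level as a covariate, where the median was -0.09.

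Ribosomal protein genes were lower by a small amount as a list (363 tested, 319 negative and 44 positive, median -0.15, camera adjusted p = 5.85e-08, and adjusted p = 0.749 with an estimated correlation). By edgeR's test 0 passed over all genes and 0 when adjusted over the list alone, with 19 at unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom. The ribosomal list's median was -0.26 with the mean marker level as a covariate (camera adjusted p = 3.12e-10, and adjusted p = 0.744 with an estimated correlation). Histone and cell cycle genes were lower as well (293 tested, 178 negative and 115 positive, median -0.08, camera adjusted p = 0.0133, and adjusted p = 0.598 with an estimated correlation). Of these, 0 passed edgeR's test over all genes and 0 when adjusted over the list alone, with 58 at unadjusted p under 0.05, 13 called by DESeq2 (2 higher, 11 lower) and 0 by limma-voom. The kinesin gene MTR_4g124650 fell with the replicate block from 102 ± 58.5 to 24.8 ± 10.4 CPM (adjusted p = 0.0426 by edgeR), and 1 fell when adjusted over the list alone. With the mean marker level as a covariate MTR_4g124650 had a log2 change of -0.64 (adjusted p = 0.591 by edgeR). The camera adjusted p of the histone and cell cycle list was 0.0527 without R108 replicate 2, 0.0670 without R108 replicate 3 and 0.0681 without Mtphr2 replicate 1. With that covariate this list's median was -0.15 (camera adjusted p = 8.92e-05, and adjusted p = 0.359 with an estimated correlation).

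The subtilase list (55 tested, 38 negative and 17 positive) was lower, with a median of -0.16 (camera adjusted p = 0.0387, and adjusted p = 0.493 with an estimated correlation). Its members include subtilisin-like serine proteases such as MTR_5g011340, at 95.7 ± 54.4 CPM in R108 and 19.0 ± 10.9 in Mtphr2, and also other genes such as subtilisin inhibitors. By edgeR's test 0 passed over all genes and 1, a nodule cysteine-rich peptide gene (MTR_3g020930), fell when adjusted over the list alone, with 10 at unadjusted p under 0.05, 5 called by DESeq2 (1 higher, 4 lower) and 0 by limma-voom, and with the replicate block 11 passed when adjusted over the list alone (1 higher, 10 lower). The list's camera adjusted p was 0.0585 without R108 replicate 2, 0.110 without R108 replicate 3, 0.114 without Mtphr2 replicate 1, 0.0644 without Mtphr2 replicate 2, 0.266 with a filter at a mean of 10 CPM and 0.0670 with the mean marker level as a covariate.

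Nodule genes, of which 13 of 679 were tested, were lower as a list (11 negative and 2 positive, median -0.59, camera adjusted p = 0.0133, and adjusted p = 0.493 with an estimated correlation). Directional fry called this list as lower too (adjusted p = 0.00328), but not with the replicate block (adjusted p = 0.0992). The leghemoglobin gene MTR_1g090820 had 6.12 ± 3.52 CPM in R108 and 2.29 ± 0.573 in Mtphr2, and the gene MTR_3g020930 for a nodule cysteine-rich peptide had 3.68 ± 0.772 and 1.15 ± 0.174 CPM. By edgeR's test 0 passed over all genes and MTR_3g020930 alone fell when adjusted over the list alone, with 4 at unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom, and with the replicate block 2 fell when adjusted over the list alone. The list's camera adjusted p was 0.0527 without Mtphr2 replicate 1. Its median was -0.79 with the mean marker level as a covariate (camera adjusted p = 0.0305, and adjusted p = 0.376 with an estimated correlation).

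WRKY factors, a family with many regulators of defence, were higher as a list in Mtphr2 (70 tested, 59 positive and 11 negative, median 0.35, camera adjusted p = 4.74e-05, and adjusted p = 0.592 with an estimated correlation). With the mean marker level as a covariate the list's median was 0.63 (camera adjusted p = 3.12e-10, and adjusted p = 0.0962 with an estimated correlation). No WRKY gene passed edgeR's test over all genes and 4 rose when adjusted over the list alone, with 19 at unadjusted p under 0.05 (18 higher, 1 lower), 9 called by DESeq2 (8 higher, 1 lower) and 0 by limma-voom. Under the replicate block 15 passed when adjusted over the list alone (14 higher, 1 lower). The 4 were MTR_4g127040 (64.5 ± 5.25 CPM in R108 and 109 ± 13.99 in Mtphr2), MTR_1g086790 (33.4 ± 1.11 and 48.2 ± 3.20 CPM), MTR_8g099350 (9.86 ± 2.82 and 34.5 ± 11.6 CPM) and MTR_7g109600 (25.2 ± 3.99 and 39.5 ± 1.26 CPM).

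NAC factors were higher as a list (65 tested, 48 positive and 17 negative, median 0.15, camera adjusted p = 0.0385, and adjusted p = 0.493 with an estimated correlation). No NAC gene passed edgeR's test over all genes and 4 rose when adjusted over the list alone, with 11 at unadjusted p under 0.05, 6 called by DESeq2 (5 higher, 1 lower) and 0 by limma-voom. The 4 were MTR_3g096920, MTR_8g094580 (42.5 ± 3.59 CPM in R108 and 76.2 ± 14.8 in Mtphr2), MTR_2g064470 (27.7 ± 2.53 and 47.5 ± 7.54 CPM) and MTR_3g088110 (13.2 ± 0.875 and 20.7 ± 1.65 CPM). The NAC gene MTR_6g011860, whose closest Swiss-Prot entry is FEZ, a factor of root cap stem cells, fell with the replicate block from 9.97 ± 12.2 to 0.870 ± 0.899 CPM (adjusted p = 0.0426 by edgeR), and 8 passed when adjusted over the list alone (5 higher, 3 lower). With the mean marker level as a covariate MTR_6g011860 had a log2 change of -0.24 (adjusted p = 0.917 by edgeR). The list's camera adjusted p was 0.0969 without R108 replicate 1, 0.0839 without Mtphr2 replicate 1 and 0.179 with the mean marker level as a covariate.

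Receptor-like kinases were higher as a list (539 tested, 355 positive and 184 negative, median 0.19, camera adjusted p = 0.0148, and adjusted p = 0.493 with an estimated correlation). The kinase gene MTR_5g055310 alone rose by edgeR's test, over all genes and when adjusted over the list alone, and the replicate block called 0 higher and 1 lower over all genes and 56 when adjusted over the list alone (33 higher, 23 lower). An unadjusted p under 0.05 was found for 122 (87 higher, 35 lower), DESeq2 called 33 higher and 13 lower, and limma-voom called 1. The list's median was 0.16 with the mean marker level as a covariate (camera adjusted p = 0.00879, and adjusted p = 0.0962 with an estimated correlation). NBS-LRR genes, the main family of intracellular immune receptors, were higher as well (516 tested, 337 positive and 179 negative, median 0.17, camera adjusted p = 0.0148, and adjusted p = 0.697 with an estimated correlation). Among the NBS-LRR genes 0 passed edgeR's test over all genes and 0 when adjusted over the list alone, with 78 at unadjusted p under 0.05, 15 called by DESeq2 (6 higher, 9 lower) and 0 by limma-voom. Without R108 replicate 3 the camera adjusted p was 0.0670 for receptor-like kinases and 0.147 for NBS-LRR genes, and without Mtphr2 replicate 1 it was 0.0596 and 0.101, as the plot of list medians shows beside the quartiles for all libraries.

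The 35 lists that did not pass had camera adjusted p of 0.0510 to 0.964. Flavonoid genes, the closest to passing, had a median of 0.35 over 110 tested members (adjusted p = 0.0510), and with the replicate block this list was higher (camera adjusted p = 0.00306, and adjusted p = 0.412 with an estimated correlation), as it was with the mean marker level as a covariate (camera adjusted p = 9.67e-08, and adjusted p = 0.451 with an estimated correlation). Aquaporin genes had a median of -0.12 over 29 tested members (camera adjusted p = 0.0670), and with the replicate block this list was lower (camera adjusted p = 0.0238, and adjusted p = 0.489 with an estimated correlation), as it was with that covariate (camera adjusted p = 0.0305, and adjusted p = 0.722 with an estimated correlation). Of the lists that mark other organs or cell layers, the nodule list passed camera as lower (adjusted p = 0.0133). The remaining lists of this kind did not pass. Their medians were 0.06 for shoot photosynthesis (50 tested, adjusted p = 0.8), 0.05 for root hairs (45 tested, adjusted p = 0.709), -0.30 for the Casparian strip (8 tested, adjusted p = 0.793) and 0.18 for seed storage and late embryogenesis genes (99 tested, adjusted p = 0.107). The mean of the root hair list was -0.07 and its camera direction was down.

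Annotation terms were counted among the called genes that differed at least 2-fold, of which 4 higher and 2 lower genes carried a term. Of 1603 terms, 0 passed Fisher's exact test, and the smallest adjusted p was 1. With the replicate block, chosen for this test after the data were examined, 7 terms passed, all among 40 lower genes with a term. The term lysosome held 7 of them out of 30 tested genes (adjusted p = 2.51e-10 by Fisher's exact test), and cysteine-type endopeptidase activity held 7 out of 63 (adjusted p = 2.17e-08 by Fisher's exact test). In both terms these were the 7 papain-type proteases, MTR_3g116080 and MTR_4g107930 among them. The other terms that passed held the same 7, and the terms peptidase activity and proteolysis also held an aspartyl protease gene. Fisher's exact test takes genes as independent, which members of 1 gene family need not be.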

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

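The count of 18 genes (17 at least 2-fold) kept within 1.5-fold under DESeq2 size factors, library size alone, upper-quartile factors, both other dispersion schemes and without the 20 most abundant genes. It was 34 (31 at least 2-fold) with no low-count filter and 9 (8) with a mean of at least 10 CPM, where other numbers of genes were tested. It was 1298 (617) with DESeq2, 31 (29) with limma-voom and 76 (72) with the replicate block, and the cause was not tested. With 1 library left out it ran from 7 to 44, and from 7 to 44 at least 2-fold, with fewer samples in each fit. Alternatives chosen after seeing the data gave 34 (34) with the arbuscule marker covariate, 1687 (997) by DESeq2 with the replicate block and 39 (39) without both replicate 1 libraries. With that covariate the calls of MTR_3g116080 and MTR_2g018710 held, and those of MTR_6g053230, MTR_2g021190, MTR_3g019090, MTR_2g084875 and MTR_5g055310 were lost at adjusted p from edgeR of 0.0587 to 0.103. For MTR_2g021190, MTR_3g019090, MTR_2g084875 and MTR_5g055310 the log2 fold changes stayed close to those without it (0.94 to 1.48 against 0.95 to 1.38). MTR_6g053230 had no counts in R108, so only a smallest fold holds for it. Of the PHR family DESeq2 called 2 in place of 0. The 13 lists called by camera became 0 with an estimated correlation, 2 with fry, 0 with an estimated correlation and the replicate block, 0 with an estimated correlation and the arbuscule marker covariate, and 8 to 16 with 1 library left out. They were 12 with the arbuscule marker covariate (7 higher, 5 lower, 6 shared with the 13) and 14 without both replicate 1 libraries (9 shared). The symbiosis signalling list reversed to higher with the marker covariate (adjusted p = 0.434, and 0.866 with an estimated correlation). Annotation terms went from 0 to 7 with the replicate block, which called more genes. The cause of the other changes was not tested. The sign of 3 genes, none of them called, reversed with 1 library left out. DMI2 (0.039 in all libraries, -0.14 to 0.38 with 1 left out) had -0.087 without R108 replicate 2, -0.14 without R108 replicate 3, -0.011 without Mtphr2 replicate 1 and -0.013 without Mtphr2 replicate 3. Without R108 replicate 1, NFP (-0.65 in all libraries, lowest -1.02) had 0.17 and MAX1 (-0.42 in all, lowest -0.63) had 0.015. Of the other values for named genes, 1203 kept their direction and side of the threshold, 62 were newly called and 39 lost their call. For lists, 535 kept their side, 21 were newly called and 64 lost their call. Over all genes by edgeR and over all lists by camera, the replicate block changed no call of a gene or list named in the text other than those given with it. At these depths, a gene with no counts in a genotype allows a level of up to 0.160 CPM.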

Other observations

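All explanations of the marker spread and of the loci present in 1 genotype, and the tests on MTR_3g116080 alone, on members with whole counts and on libraries with whole counts, were set up after the results they measure were seen. Many genes followed the mean marker level within genotypes. A fit with genotype and marker level called 308 genes for the marker level, 303 rising with it, among them 12 of the 17 markers that define it. Apart from the markers, 7 of 30 tested germin-like genes, 14 of 199 cytochrome P450 genes and 9 of 81 nitrogen transport genes rose with it. The LysM protein gene MTR_4g091010 had a slope of 0.95 (adjusted p = 0.00228 by edgeR), and the cyclin-dependent kinase gene MTR_8g092290 had 0.96 (adjusted p = 0.00287 by edgeR).

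With the marker level held equal by a fitted line, the same fit called 34 genes for the genotype, of which 26 were higher in Mtphr2. Marker means overlapped only between R108 replicate 3 (4.56) and Mtphr2 replicate 1 (4.81), so these values rest largely on extrapolation. These held 3 of 70 WRKY genes and 2 of 110 flavonoid genes, and 0 of 516 NBS-LRR and 0 of 72 pathogenesis-related genes. As a list the NBS-LRR genes were higher in this fit (median log2 fold change 0.31, camera adjusted p = 5.01e-06, and adjusted p = 0.365 with an estimated correlation), against 0.17 without the covariate (camera adjusted p = 0.0148, and adjusted p = 0.697 with an estimated correlation). The WRKY gene MTR_2g105060 had a log2 fold change of 3.98 (adjusted p = 0.0275 by edgeR) and the WRKY gene MTR_8g099350 had 2.67 (adjusted p = 0.0275 by edgeR). The 2-hydroxyisoflavanone dehydratase gene MTR_1g105020, of isoflavone synthesis, had 1.82 (adjusted p = 0.0132 by edgeR). The nitrate transporter gene MTR_7g088820 had 2.01 (adjusted p = 0.0497 by edgeR). The genes named here were chosen after their values were seen. Without the covariate none of them was called, with adjusted p from edgeR of 0.123 to 0.268. Their log2 fold changes were then 2.33 for MTR_2g105060, 1.81 for MTR_8g099350, 0.89 for MTR_1g105020 and 1.40 for MTR_7g088820.

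The arbuscule markers differed several-fold among libraries of each genotype. Counting noise between technical replicates was excluded as the cause, since the median ratio of variance to mean was 655 where such noise gives about 1. The spread was not shared by all genes, since the median SD of all genes was 0.183 times that of the markers. Levels were scaled by library first, and RNA quality need not act on all genes alike, so it was not excluded. Different amounts of arbuscule-bearing root per library fit, since 92.3% of the markers' variance within genotypes lay on 1 component. Random lists had a 95th percentile of 84.8% and a highest value of 96.8%. Any cause that moves the markers together would give this too, so the amount of such root was not singled out. Whether Mtphr2 roots may also hold fewer arbuscules could not be told from this test, since the 92.3% was measured within genotypes.

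Papain-type proteases and chitinases fell together with the replicate block. The group's median log2 fold change was -0.656 (SD 1.77) with the marker covariate against -4.03 without it. This SD includes MTR_3g116080 at -5.81, while the other members had -0.731 to -0.273. From R108 replicate 3 to Mtphr2 replicate 1, whose marker means lay near each other, the members' median log2 difference was -0.508. That of the markers was 0.124. But 0 of 9 members had a called slope on the marker level (adjusted p from 0.0675 to 0.147 by edgeR). Also, MTR_4g107930 had 21.7 and 21.2 CPM in R108 replicates 2 and 3, where the marker mean was 5.91 and 4.56. Whether the group follows the marker level was therefore left open. For MTR_3g116080 alone, following the marker level was excluded, since its value with the covariate was -5.81. In R108 replicates 1 to 3 this gene had 94.1, 102 and 128 CPM while the marker mean went from 7.05 to 4.56. Counts that were not whole were found in 66.7% of members, and those of MTR_4g080700 and MTR_4g080730 added up to whole numbers in all 4 libraries where both had them. The summed CPM of these 2 genes had a log2 difference of -4.37 between Mtphr2 and R108. Sharing between these 2 alone leaves their sum unchanged, so it does not account for their joint fall. The fall was also present where counts were whole. Members with whole counts had a median of -4.18 with the replicate block, and 4 others had a median difference of -4.65 (SD 0.285) in pairs of libraries where their counts were whole. All 9 members were chosen for having fallen, and a whole count does not show that no reads were shared. Apart from sharing between MTR_4g080700 and MTR_4g080730 alone, reads split between copies were therefore not excluded as a cause.

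At 26 loci, expression was at least 1 CPM in all libraries of 1 genotype and at most 0.1 times that in all of the other, 10 in R108 and 16 in Mtphr2, and these include MTR_3g116080 and in all 12 of the 18 genes called by edgeR. Values within genotypes argue against arbuscule content as the cause for these loci. In the genotype where they were on, their median SD of log2 CPM was 0.245, against 1.27 for the markers within genotypes. Also, 16 of the loci were on in Mtphr2, where marker levels were lower. The median absolute log2 fold change of 7.25 with the marker covariate (SD 1.55) cannot decide this. It is large by the choice of the loci, as marker means overlap between genotypes. A sequence difference between the lines, such as a deletion or a different background near the mutation, fits, since 65.4% of the loci were assembled outside the annotation against 4.77% of all tested genes (p = 6.21e-17, Fisher's exact test). Whether these loci lie together on a chromosome was not tested.

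The splits of the libraries into groups of 3 are too few for a share under 0.05. The real split was 1 of 10 for the number of these loci (highest other split 5), for genes called by edgeR (highest other 0) and for genes called at least 2-fold (highest other 0). With the replicate block it was 1 of 4 (highest other 0). By DESeq2 it was 1 of 10, and the highest other split, R108 replicates 1 and 2 with Mtphr2 replicate 1 against the rest, gave 516 genes, and a split of R108 replicates 1 and 3 with Mtphr2 replicate 1 gave 351. The other splits that keep both replicate 1 libraries together, with Mtphr2 replicate 2 or Mtphr2 replicate 3, gave 24 and 58. The replicate number alone does not account for this difference, and whether it does so together with genotype was not tested. The split with 516 sets apart the 3 libraries with the highest marker means (7.05, 5.91 and 4.81).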
